A study of Mus musculus with 12 samples.

How the data were processed

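RNA from 12 pancreas samples of mice aged 6 months, 6 samples of the control genotype and 6 with the HuR transgene per the labels, was hybridised as biotin-labelled cDNA to 1 array each. The labels' protocols state that tissue was kept in RNAlater, that RNA was purified with a Qiagen protocol and that samples of sufficient RNA quality were used. The deposited values are log2 expression values from RMA, which corrects background, normalizes between arrays and summarises probes per transcript cluster, per the labels. The submitters' processing notes name Affymetrix Expression Console 1.4 and Transcriptome Analysis Console 3.1, and the settings are not given in the sources used here.

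Each array held 72688 rows, of which 6732 control rows were left out and 65956 were tested. Through the annotation of the platform 30607 rows had 1 gene symbol, 2143 had several and were not named, and 33206 had none there. Symbols were updated through the gene identifier with a RefSeq table of assembly GRCm38.p6, used for names and for the order of neighbouring genes only. It matched 22821 rows and updated 827 symbols, while other rows kept the symbol of the annotation, which can be old. For genes with several rows the row with the highest mean over all 12 arrays was taken, which left 30145 genes.

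Array medians were 4.42 to 4.60. The 23 background rows had a median of 3.74, and 18030 genes lay above the median row level of 4.516. The scale ended at 19.9, the log2 of 999952, and 139 genes stood there on all 12 arrays. The same value on 3 or more arrays, called a plateau here, was found in 936 genes, and its cause is not known here. A plateau is not simply an upper limit, since Dcn held 16.399 on 4 arrays and reached 17.81 on HuR replicate 2. Differences of genes at the end of the scale are hidden, and those of genes on a plateau may be compressed. The correlation between arrays was 0.971 to 0.996 over genes, no 2 arrays held the same values, and no array was left out of the main comparison.

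Samples were grouped by the titles and genotypes in the labels. The difference between HuR and control was fitted on all rows with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with data.table (version 1.17.8) for reading and Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05, and a second count asked for a 2-fold difference. Exact permutation tests used all 924 assignments of the 12 arrays to groups of 6, so the smallest two-sided p was 0.00216. Intervals of list differences were 95% intervals from the spread between arrays.

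A total of 32 gene lists with 684 entries were fixed before the data were examined, as were the main design and the alternatives listed first below. They covered acinar enzymes, acinar transcription factors, ducts, pancreatitis response, islets, matrix, stellate cells, macrophages, T and NK cells, B and plasma cells, lymph node, neutrophils, mast cells with eosinophils and basophils, dendritic cells, chemokines, antigen presentation, interferon response, complement, ER stress, cell cycle, apoptosis, described HuR targets, AU-rich element binding proteins, immediate early genes, the clock, adipocytes, endothelium, nerve with mesothelium, red blood cells, liver and intestine, muscle and sex-linked genes. Lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. Counts of members past the threshold were taken over all genes and adjusted over the list alone.

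The genes to name were fixed by a rule. They were Elavl1, the 6 genes with the highest and the 6 with the lowest fold change among those past the threshold or, as none passed, the 5 with the smallest p in each direction, leaving out predicted genes, Riken clones, small RNAs and immunoglobulin or T cell receptor segments. For each list they were the 2 members with the smallest p past the threshold or, as none passed, the brightest member. Other genes are said to be chosen after their values were seen.

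The fit was tested on simulated data for the comparison of HuR and control, in which 30145 genes varied independently of each other with their measured spread. Of 50 genes changed by each size, 74% were recovered at a log2 change of 0.5, 96% at 1 and 100% at 2 and 4, and 11 of 196 calls were false. Of the simulated lists, 5 of 5 shifted and 0 of 15 unshifted ones were called. Measured genes of a list vary together, with estimated correlations up to 0.764, so this does not give the rate of false list calls in the measured data. The recovery rates hold for 200 changed genes that vary independently, and Lgals9, at a measured difference of 3.61, was not called.

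Alternatives planned in advance were the replicate number as a block, a filter at the median row, 2 other normalizations, the mean of a gene's rows, other variance settings, array weights, covariates for Xist, B cell and islet levels, each array left out in turn, a looser threshold of 0.1 and the estimated correlation. Chosen after seeing the data were a covariate for adipocyte level, the omission of control replicate 2 and HuR replicate 2 together, the omission of genes on a plateau, the omission of each list's member with the largest difference and the exact permutation of list means. Control replicate 2 and HuR replicate 2 were the arrays highest on the first principal component, which held 44% of the variance. Figures were drawn with matplotlib 3.10.9.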

Results

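12 samples of pancreas from mice aged 6 months were profiled on Affymetrix expression arrays. The control group held 6 samples of the genotype Pdx1/Cre, in which Cre recombinase is driven by the promoter of the pancreatic gene Pdx1. The HuR group held 6 samples that also carried the Traffic-HuR transgene. HuR, encoded by Elavl1, is an RNA-binding protein that recognises AU-rich elements in messages. The comparison asked how gene expression in the pancreas differed when HuR was elevated. Expression is given as log2 values as deposited, means are followed by the SD over 6 arrays, and differences are HuR minus control with their standard error (SE). The number of arrays limits the precision of each value. The labels do not say whether each array held a separate mouse. All p-values treat the 12 arrays as independent, and may be too small if some came from the same mouse.

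Elavl1 was 1.18-fold higher in the HuR samples. Its level was 5.99 ± 0.12 (SD, n = 6) in the controls and 6.23 ± 0.14 (SD, n = 6) in the HuR samples, a difference of 0.24 (SE 0.076), with an exact two-sided permutation p of 0.0108. In 5 of 6 HuR arrays the level lay above every control array. The limma adjusted p over all genes was 0.878, and which part of the transgene's message the probes of this row cover is not known here.

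No gene passed the threshold over all genes, and 6 genes shared the smallest adjusted p of 0.437. Leaving out predicted genes and immunoglobulin segments, these were Lgals9 and Glp1r. Lgals9, which encodes the carbohydrate-binding protein galectin-9, was 12.2-fold higher, at 11.45 ± 1.58 (SD, n = 6) against 7.84 ± 0.42 (SD, n = 6). Glp1r, the receptor of the incretin hormone GLP-1, was 1.71-fold lower, at 13.98 ± 0.09 against 14.75 ± 0.32. Each separated the genotypes in 6 of 6 HuR arrays. Their exact permutation p was 0.00216, the smallest that 12 arrays in groups of 6 can give.

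With the same genes left out, those next in p and higher in HuR samples were Rap1a, a small GTPase, with a difference of 0.41 (SE 0.075), the protein kinase C isoform gene Prkch with 0.21 (SE 0.039), Tmem229a with 0.17 (SE 0.034) and the inhibitory immune receptor gene Lair1 with 0.24 (SE 0.050). Those lower were Ptprn2, a phosphatase-family protein of secretory granules, with -0.78 (SE 0.171), the receptor phosphatase genes Ptprf with -0.34 (SE 0.069) and Ptprd with -0.27 (SE 0.059), and the transcription factor gene Tbx18 with -0.23 (SE 0.049). Their limma adjusted p ran from 0.543 for Rap1a to 0.778. Each separated the genotypes in 6 of 6 HuR arrays, except Lair1 with 5.

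**Figure D1:**
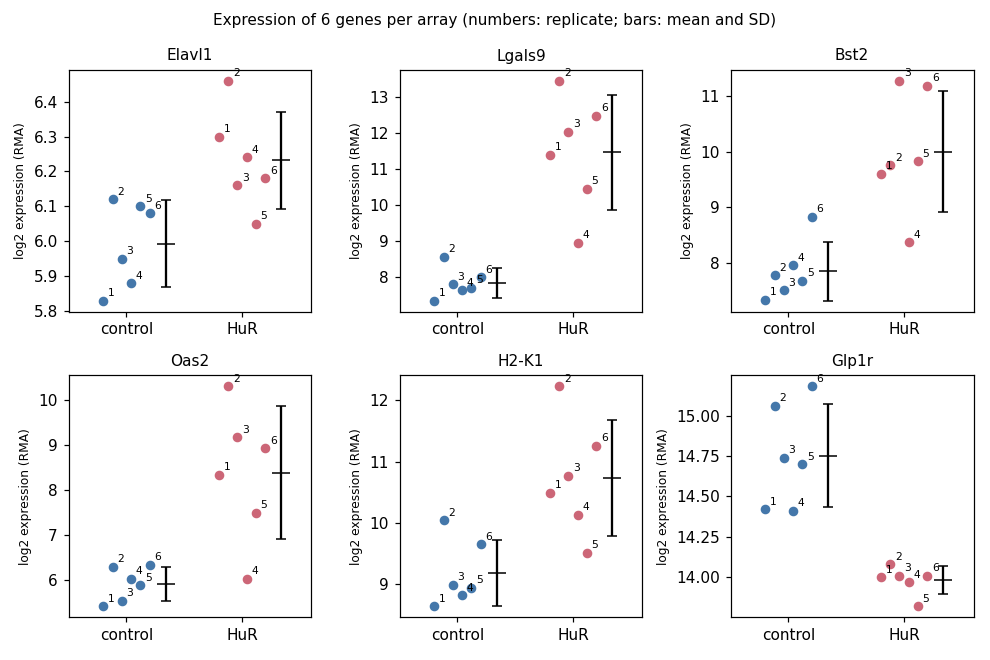
Log2 expression (vertical axis) of 6 genes on each of the 6 control arrays (blue) and 6 HuR arrays (red), numbered by replicate, with bars for the mean and SD. Lgals9 lies between 7.35 and 8.57 in the controls and between 8.95 and 13.44 in the HuR samples, while Glp1r lies lower in every HuR array than in any control array; no gene passed the adjusted threshold.

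Over the 30145 genes, limma called 0 at an adjusted p under 0.05 and therefore 0 at a 2-fold difference. At an unadjusted p under 0.05 there were 1657 genes, 864 higher and 793 lower in HuR samples, where chance gives 1507. The ordinary linear model without variance moderation gave 1611 such genes and also called 0. Among genes with an unadjusted p under 0.05 and at least a 2-fold difference, 100 were higher and 1 was lower. The gene that was lower, chosen after its values were seen, was Hamp2, a hepcidin gene, at -1.05 (SE 0.424). Its lowest value was 12.071 in HuR replicate 2. Without control replicate 2 and HuR replicate 2 it differed by -0.756 (SE 0.249), less than 2-fold. The genotypes did not overlap in 50 genes that were higher and 40 that were lower, 0.299% of all genes, where chance gives 0.216%.

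All 25 measured genes of the interferon response had a higher mean in the HuR samples, 17 of them at an unadjusted p under 0.05. The list mean was 6.58 ± 0.55 (SD, n = 6) against 5.82 ± 0.25 (SD, n = 6), a difference of 0.75 (SE 0.247) with a 95% interval from 0.20 to 1.30, or 1.68-fold. Oas2, an antiviral oligoadenylate synthetase gene, had a difference of 2.46 (SE 0.576) and was 5.51-fold higher. Bst2, which encodes the antiviral membrane protein tetherin, had a difference of 2.16 (SE 0.457) and was 4.46-fold higher. Both lay above all controls in 5 of 6 HuR arrays, with HuR replicate 4 inside the control range. The interferon-regulated protease gene Usp18 had a difference of 1.30 (SE 0.402), and the interferon-inducible GTPase gene Igtp 1.25 (SE 0.422). Over all genes 0 members passed the limma threshold, and 17 did when adjusted over the list alone. Oas2, Usp18 and Igtp, like the members named next for antigen presentation and macrophages, were chosen after their values were seen, among members past the threshold when adjusted over their list alone.

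The test of the interferon list with camera gave an adjusted p of 3.74e-22 with a preset correlation and an adjusted p = 0.193 with an estimated correlation. An exact permutation of the list mean gave p = 0.013, or 0.139 after adjustment over the 32 lists. Without control replicate 2 and HuR replicate 2, 2 arrays that stood apart from the rest, the difference was 0.69 (SE 0.222) and 18 members passed when adjusted over the list alone. There the camera adjusted p was 0.165 with an estimated correlation. With the mean of the adipocyte list as a covariate the interferon list differed by 0.47, and with the mean of the macrophage list by 0.388 (SE 0.165).

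Antigen-presentation genes were also higher, with 17 of 18 measured members higher and 1 lower. The list mean was 7.69 ± 0.43 (SD, n = 6) against 7.08 ± 0.33 (SD, n = 6), a difference of 0.62 (SE 0.221) with a 95% interval from 0.13 to 1.11. The class I genes H2-K1 and H2-D1 differed by 1.56 (SE 0.411) and 1.27 (SE 0.351), and the class II genes H2-Eb1 and H2-Ab1 by 1.44 (SE 0.462) and 1.37 (SE 0.532). These histocompatibility genes have close relatives, so their values are uncertain where a probe matches more than 1 gene. B2m, the class I light chain, differed by 1.25 (SE 0.374) and held the same high value on 3 arrays. No member passed over all genes with limma, and 10 did when adjusted over the list alone. The camera adjusted p was 1.33e-11 with a preset correlation, and the adjusted p = 0.214 with an estimated correlation. The exact permutation p of the list mean was 0.026. The difference fell to 0.33 with the adipocyte mean as a covariate.

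Macrophage and monocyte markers were higher in 24 of 25 measured genes, with 7 at an unadjusted p under 0.05. The list mean differed by 0.56 (SE 0.319), with a 95% interval from -0.15 to 1.27 and an exact permutation p of 0.108. The lysosomal protease gene Ctss differed by 1.71 (SE 0.545), the pore-forming protein gene Mpeg1 by 1.29 (SE 0.307), Ms4a7 by 0.84 (SE 0.221) and the beta-glucan receptor gene Clec7a by 0.78 (SE 0.203). Lyz2, the brightest member, differed by 0.90 (SE 0.906), and by -0.387 to 1.53 over the alternatives. Adjusted over the list alone, 5 members passed, and 0 passed over all genes with limma. The camera adjusted p was 1.46e-11 with a preset correlation, and the adjusted p = 0.329 with an estimated correlation. Without both arrays that stood apart, the list differed by 0.50 (SE 0.178) and 13 members passed when adjusted over the list alone. There the camera adjusted p was 0.165 with an estimated correlation, while without HuR replicate 2 alone the list differed by 0.33. With the B cell mean as a covariate it differed by 0.31, and with the adipocyte mean by 0.09, where its camera call was lost.

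**Figure D2:**
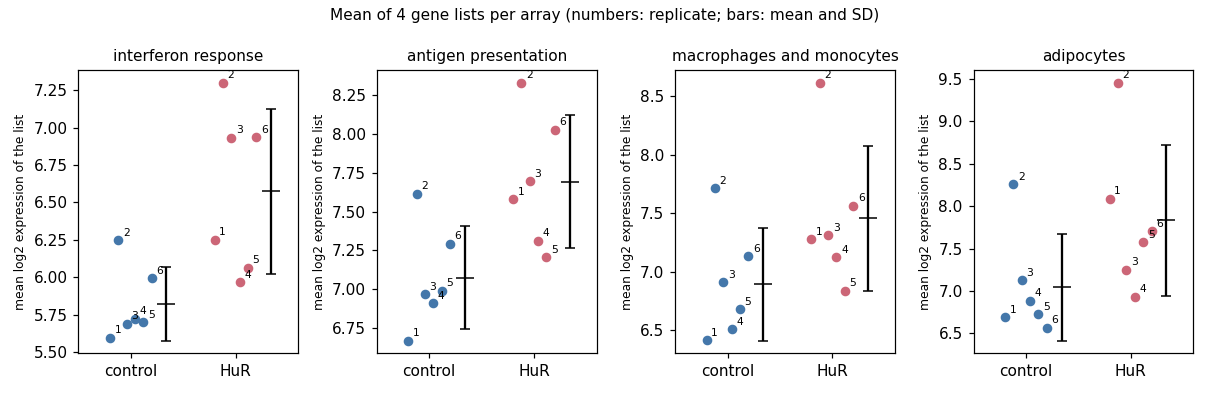
Mean log2 expression (vertical axis) of the interferon response, antigen presentation, macrophage and adipocyte lists on each of the 6 control arrays (blue) and 6 HuR arrays (red), numbered by replicate, with bars for the mean and SD. Control replicate 2 and HuR replicate 2 are the highest of their group in all 4 lists, at 6.25 and 7.30 for the interferon list and 8.26 and 9.45 for the adipocyte list.

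Markers of other immune cells had small differences at low levels. T and NK cell genes were higher in 22 of 25 measured members, of which only 11 lay above the median level of all rows, and the list mean differed by 0.15 (SE 0.046), or by 0.26 over genes above the median row alone. Dendritic cell genes were higher in 14 of 16, with a list difference of 0.18 (SE 0.046), and Bst2 alone passed when adjusted over the list alone. Without Bst2, which is also in the interferon list, the dendritic list was still called but differed by only 0.05 (SE 0.035), with an exact permutation p of 0.167. Neutrophil genes were higher in 15 of 18, with a list difference of 0.11 (SE 0.043), and Lcn2, an iron-binding protein of neutrophils and injured epithelium, differed by 0.37 (SE 0.119). The exact permutation p of these list means was 0.00866, 0.00433 and 0.0216, each 0.139 after adjustment. All 3 lists were called by camera with a preset correlation, and the adjusted p = 0.193 for T and NK cells and 0.212 for dendritic cells and for neutrophils with an estimated correlation. The neutrophil call was lost when only genes above the median row were tested, at a difference of 0.16, and with the islet mean as a covariate, at 0.08. The dendritic cell call was lost with the adipocyte mean as a covariate, at 0.14.

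B and plasma cell genes were higher in 15 of 20 members and the list differed by 0.24 (SE 0.248), which camera did not call at an adjusted p of 0.0785 with a preset correlation, and the adjusted p = 0.803 with an estimated correlation. Without control replicate 2, whose B cell list mean of 6.04 lay far above the other controls, the list differed by 0.42 and was called with a preset correlation, as it was at 0.29, 0.29 and 0.33 without HuR replicate 3, 4 or 5 and at 0.325 (SE 0.162) without both arrays that stood apart, where the adjusted p = 0.398 with an estimated correlation. It fell to 0.14 without HuR replicate 2 and to 0.15 without Ighm, and was not called there. It was also called with a block for the replicate number, at 0.24, after a new quantile normalization, at 0.23, and with array weights, at 0.26. With the adipocyte mean as a covariate it turned to -0.12 and was called lower, and with the islet mean as a covariate it was called higher at 0.43. Ighm, the IgM heavy chain, differed by 1.94 (SE 1.32), and by -0.196 to 2.87 over the alternatives. Lymph node genes differed by -0.12 (SE 0.255), with Cxcl13, a B cell chemokine, at -0.79 (SE 1.98), and mast cell, eosinophil and basophil genes by -0.02 (SE 0.072), with Kit at 0.07 (SE 0.173). Neither list was called, and with single arrays left out they ran from -0.28 without HuR replicate 2 to 0.02 without control replicate 2, and from -0.07 to 0.02 without the same arrays.

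Among chemokine and cytokine genes, 26 of 36 were higher and 10 lower, and the list differed by 0.13 (SE 0.146) with an exact permutation p of 0.416. The chemokine genes Ccl8 and Cxcl9, chosen after their values were seen, differed by 1.83 (SE 0.517) and 1.81 (SE 0.624). Complement genes were higher in 12 of 13 members, with a list difference of 0.42 (SE 0.4), an exact permutation p of 0.338 and Serping1, the C1 inhibitor gene, at 0.18 (SE 0.63). Both lists were called by camera with a preset correlation, at adjusted p values of 0.00341 and 0.009, and the adjusted p = 0.263 and 0.618 with an estimated correlation. Without HuR replicate 2 the differences were 0.04 for chemokines and 0.16 for complement, and without control replicate 2 they were 0.20 and 0.68, while chemokines differed by 0.07 without control replicate 1 and by 0.08 without Ccl8. With the islet mean as a covariate they were 0.21 and 0.84, and over genes above the median row chemokines differed by 0.19. The complement call was lost without HuR replicate 2, without control replicate 1, 4 or 5 and when only genes above the median row were tested, at 0.44. With the B cell mean as a covariate both calls were lost, at 0.002 for chemokines and 0.10 for complement. With the adipocyte mean as a covariate the chemokine mean turned to -0.08 and its call was lost, while complement turned to -0.19 and was called lower.

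Adipocyte markers were higher in 16 of 17 measured genes, 3 of them at an unadjusted p under 0.05. The list differed by 0.79 (SE 0.443), with a 95% interval from -0.20 to 1.78 and an exact permutation p of 0.0996. Car3, a carbonic anhydrase abundant in fat, differed by 2.64 (SE 1.02) and was 6.23-fold higher, with an exact permutation p of 0.0455. The adipokine genes Retn and Adipoq, chosen after their values were seen, differed by 2.11 (SE 0.929) and 1.38 (SE 0.64). Retn stood at 13.917 in HuR replicate 2 against at most 10.486 in the other HuR arrays. Without both arrays that stood apart, Retn differed by 1.63 (SE 0.454) and Adipoq by 1.49 (SE 0.414). The camera adjusted p was 3.95e-07 with a preset correlation, the adjusted p = 0.347 with an estimated correlation, and 0 members passed when adjusted over the list alone or over all genes. Without both arrays that stood apart the list differed by 0.71 (SE 0.219), with an exact permutation p of 0.0159 and 10 members past the threshold when adjusted over the list alone. There the exact permutation p adjusted over the lists was 0.102, and the camera adjusted p was 0.165 with an estimated correlation. Without HuR replicate 2 alone the list differed by 0.47, and with the B cell mean as a covariate by 0.44.

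Islet genes were lower in 23 of 24 measured members in the HuR samples, 2 of them at an unadjusted p under 0.05. The list differed by -0.47 (SE 0.342), with a 95% interval from -1.24 to 0.29 and an exact permutation p of 0.193, and in 6 of 6 HuR arrays it lay below the control median. Iapp, the beta cell peptide amylin, differed by -0.86 (SE 0.679) and held the same value on 3 arrays, so its difference may be compressed. Ins2 and Gcg, chosen after their values were seen, held the same value on 10 and 6 arrays, so their differences of -0.02 and -0.22 are not informative. The camera adjusted p was 1.16e-06 with a preset correlation, the adjusted p = 0.358 with an estimated correlation, and 0 members passed when adjusted over the list alone. Without control replicate 2, in which the islet list stood at 10.42, the difference was -0.22, and without both arrays that stood apart -0.31 (SE 0.263). It was -0.84 with the adipocyte mean as a covariate.

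Most digestive enzymes of acinar cells could not be compared. Of the 28 measured genes, which include trypsinogens, chymotrypsinogens, elastases, lipases and amylase, 26 stood at the upper end of the scale on all 12 arrays, among them Cel, the bile salt-activated lipase. The list difference of -0.02 (SE 0.015) therefore sets no bound on their change. Ctrc, a chymotrypsin C gene that the annotation marks as a transcribed pseudogene, was the only member without a plateau and differed by -0.54 (SE 0.265). Transcription factors and granule regulators of acinar cells were measurable and were lower in 12 of 13 members, with a list difference of -0.17 (SE 0.137) and an exact permutation p of 0.249. Bhlha15, which encodes the acinar secretory factor Mist1 and was chosen after its values were seen, differed by -0.64 (SE 0.264), Ptf1a by -0.07 (SE 0.194), and Tmed6, on a plateau on 7 arrays, by -0.11 (SE 0.18). Camera called this list with a preset correlation at an adjusted p of 0.0147, and the adjusted p = 0.506 with an estimated correlation. The call was lost without control replicate 6, at a difference of -0.12, and without HuR replicate 2, at -0.09, while without control replicate 2 the difference was -0.26 and with the islet mean as a covariate -0.27. It was also lost with the B cell mean as a covariate, at -0.07. With the adipocyte mean as a covariate the difference turned to 0.02.

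Pancreatitis-response genes were higher in 13 of 20 members and lower in 2, while Reg1 and Tff2 were among 4 members at the upper end of the scale. Nupr1, Reg1, Reg3d, Spink1 and Tff2 held 1 value on all 12 arrays and could not be compared. With Clu, on a plateau on 8 arrays, 6 members were on a plateau. The list differed by 0.38 (SE 0.193), with an exact permutation p of 0.0736. The regenerating-islet-derived genes Reg3g, Reg3b and Reg2, chosen after their values were seen, differed by 2.24 (SE 0.804), 1.82 (SE 1.29) and 1.35 (SE 0.952). For Reg3g the exact permutation p was 0.00649, and its level in HuR replicate 5 was 12.09 against at most 8.10 in the other HuR arrays. Reg3b was also highest there, at 19.731 against at most 16.365 in the other HuR arrays, while control replicate 3 reached 18.355. Camera called the list with a preset correlation at an adjusted p of 0.00552, and the adjusted p = 0.193 with an estimated correlation. With the adipocyte mean as a covariate the call was lost, at a difference of 0.28.

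Matrix, fibroblast and duct genes were not called as lists in the main comparison. Of 32 matrix genes, 18 were higher and 14 lower, and the list differed by 0.05 (SE 0.222), with a 95% interval from -0.44 to 0.55, and the adjusted p = 0.803 with an estimated correlation. Dcn, the collagen-binding proteoglycan decorin, differed by 0.09 (SE 0.326) and Col1a1, chosen after its values were seen, by -0.16 (SE 0.295). Without HuR replicate 2 the matrix list turned to -0.13 and was called lower, while without control replicate 2, HuR replicate 4 or HuR replicate 6 it was called higher, at 0.13, 0.12 and 0.10, each with a preset correlation, and without control replicate 1 it was -0.01. Adipocyte and islet covariates brought opposite calls, lower at -0.30 and higher at 0.18. Stellate cell and fibroblast genes were split 10 and 10, with a list difference of -0.14 (SE 0.24), while Dpt differed by -0.29 (SE 0.647) and Acta2, also chosen after its values were seen, by 0.10 (SE 0.188). Without HuR replicate 2 this list differed by -0.33, and without both arrays that stood apart by -0.23 (SE 0.14), and was called lower in each case with a preset correlation. In the latter case the adjusted p = 0.398 with an estimated correlation, and over all arrays 0.803. It was also called lower with array weights (-0.22) and with the adipocyte mean (-0.47) or the B cell mean (-0.29) as a covariate. Toward 0 it moved to -0.04 without control replicate 2, -0.07 without control replicate 6 or HuR replicate 5 or 6, -0.08 without HuR replicate 3, -0.07 without Igfbp5 and -0.01 with the islet mean as a covariate. Duct and acinar-to-ductal metaplasia genes differed by 0.04 (SE 0.058), or -0.01 without HuR replicate 2, and Krt19, a duct keratin chosen in the same way, by -0.28 (SE 0.165).

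**Figure D3:**
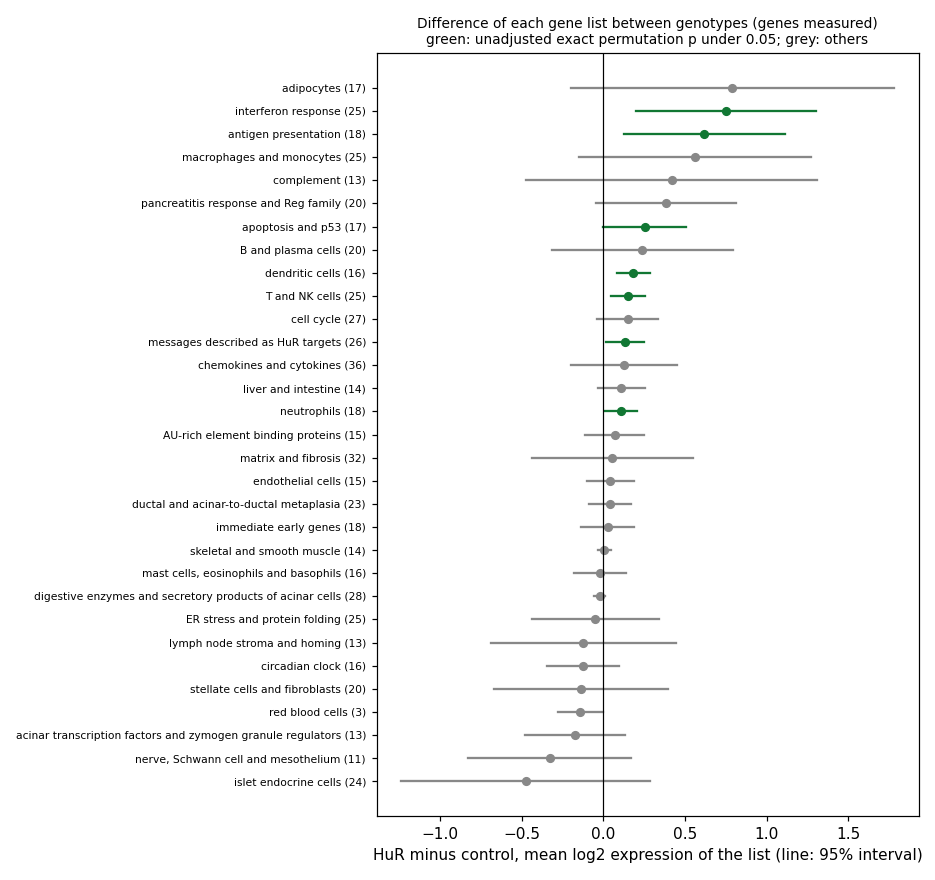
Difference of the mean log2 expression of each gene list, HuR minus control (horizontal axis), with 95% intervals over 6 and 6 arrays and the number of measured genes in parentheses. Green marks the 7 lists with an unadjusted exact permutation p under 0.05; the interferon list has a difference of 0.75, and after adjustment no list passed, the smallest adjusted p being 0.139.

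Messages described as HuR targets were slightly higher, in 22 of 26 members. The list differed by 0.13 (SE 0.053), or 1.09-fold, with a 95% interval from 0.01 to 0.25 and an exact permutation p of 0.0173, and its brightest member Actb differed by 0.21 (SE 0.248). Apoptosis and p53 genes differed by 0.25 (SE 0.114), with an exact permutation p of 0.0411 and the p53 target Ccng1 at 0.78 (SE 0.323). Cell cycle genes were higher in 25 of 27 members, with a list difference of 0.15 (SE 0.084) and an exact permutation p of 0.0584, and Pcna differed by 0.24 (SE 0.122). These 3 lists were called by camera with a preset correlation, and the adjusted p = 0.193, 0.283 and 0.352 with an estimated correlation. In none of them did a member pass when adjusted over the list alone. The HuR target list shares Cdkn1a, Mdm2, Bcl2, Mcl1 and Xiap with the apoptosis list and Ccna2 and Ccne1 with the cell cycle list. It is therefore not separate from either. HuR targets differed by 0.087 without HuR replicate 2, by 0.089 without both arrays that stood apart and by 0.094 (SE 0.043) without Cdkn1a. Without HuR replicate 2 the cell cycle list differed by 0.08 and the apoptosis list by 0.17, where its call was lost. Without both arrays that stood apart these 2 lists differed by 0.08 and 0.17. The apoptosis call was lost too with the B cell mean as a covariate, at 0.21. With the adipocyte mean as a covariate all 3 calls were lost, at 0.07 for HuR targets, 0.16 for apoptosis and 0.02 for the cell cycle.

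Nerve, Schwann cell and mesothelium genes were lower in 9 of 11 members, with a list difference of -0.33 (SE 0.224) and the mesothelial gene Upk1b at -0.89 (SE 0.608). Camera called the list at an adjusted p of 0.0438 with a preset correlation, and the adjusted p = 0.339 with an estimated correlation. The call was lost without control replicate 2, at -0.19, and without any of control replicate 1 or HuR replicates 1, 3, 5 and 6, at -0.38 to -0.25. It was also lost after a new quantile normalization, at -0.36, with the islet mean as a covariate, at -0.16, and without Upk3b, at -0.26. The list stayed called with the adipocyte mean as a covariate, at -0.61.

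The remaining lists were not called in the main comparison. Their differences were -0.05 (SE 0.175) for ER stress and protein folding, 0.07 (SE 0.082) for AU-rich element binding proteins, 0.02 (SE 0.074) for immediate early genes, -0.13 (SE 0.099) for the circadian clock, 0.04 (SE 0.065) for endothelial cells, -0.14 (SE 0.063) for 3 red blood cell genes, 0.11 (SE 0.064) for liver and intestine and 0.01 (SE 0.017) for muscle. In 4 lists that were not called the median change had the opposite sign to the mean, at -0.009 for liver and intestine, -0.005 for muscle, -0.06 for sex-linked genes and 0.001 for stellate cells. Their brightest members differed by -0.10 for Sel1l, which sat on a plateau on 9 arrays, -0.01 for Pum2, 0.10 for Btg2, -0.37 (SE 0.154) for Clock, 0.01 for Kdr, -0.36 (SE 0.148) for Alas2, 0.73 (SE 0.789) for Trf and -0.08 for Smtn. With a preset correlation, leaving out 1 array brought a call for ER stress (-0.14 without control replicate 4), AU-rich element binding proteins (0.11 without control replicate 2 and 0.10 without HuR replicate 3), the clock (-0.16 without control replicate 4 or 5 and -0.18 without HuR replicate 4), endothelial cells (0.09 without control replicate 6, 0.07 without HuR replicate 3 and 0.06 without HuR replicate 6) and red blood cells (-0.17 without HuR replicate 1). With other arrays left out the same lists moved toward 0 or past it, ER stress to 0.06 without HuR replicate 4 and 0.01 without control replicate 1 or 5, the clock to -0.06 without control replicate 6, and AU-rich element binding proteins and endothelial cells to 0.01 without HuR replicate 2. Immediate early genes ran from -0.01 to 0.06 and muscle from -0.01 to 0.01. Liver and intestine genes differed by 0.294 over genes above the median row and by 0.0324 with the adipocyte mean as a covariate. The islet mean as a covariate brought a call for AU-rich element binding proteins, at 0.13. Over all arrays the camera adjusted p = 0.379 to 0.803 with an estimated correlation for the 5 lists that gained a call. The sex-linked genes differed by 0.33 (SE 0.418), and by -0.02 without control replicate 6, which had low values of Xist and of Y-linked genes. With a preset correlation camera called 16 of the 32 lists, 13 higher and 3 lower. With an estimated correlation it called 0, with 7 at an unadjusted p under 0.05, and the smallest adjusted p was 0.193.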

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

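The comparison of the adipocyte and B cell lists and the counts of called genes over other splits were tests chosen after the result was seen, as was the omission of control replicate 2 and HuR replicate 2. Of 186 groups of 6 arrays examined, 14 held an array whose gap to the nearest other, divided by the range of the group, exceeded the 95% limit. Chance flags about 1 in 20 groups, or 9.3 here. Of the 14, 10 were control replicate 2 and 4 were HuR replicate 2.

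Control replicate 2 stood far above the other controls in 10 cases. The gap was 0.838 of the range for the B and plasma cell list mean (6.04 against at most 4.98), 0.669 for the adipocyte list mean (8.26 against at most 7.13), 0.638 for the complement list mean, 0.716 for the list of mast cells, eosinophils and basophils and 0.66 for the list of nerve and mesothelium. Among genes it was 0.705 for Upk1b (11.15 against at most 9.01), 0.673 for Trf (13.21 against at most 10.59), 0.697 for Ciita, 0.638 for Tap1 and 0.676 for Usp18. HuR replicate 2 stood above the other HuR samples by 0.702 of the range for the duct list mean, 0.657 for the list of stellate cells and fibroblasts, 0.641 for the complement list mean and 0.703 for Serping1 (14.39 against at most 12.11).

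The adipocyte list was higher in HuR samples by 0.789 (SE 0.443), and by 0.708 (SE 0.219) without the 2 arrays that stood apart. Each is the highest of its group, so leaving out both cannot show what either carries. Left out singly, the difference was 0.465 without HuR replicate 2 and 1.03 without control replicate 2, so neither alone removes it. A candidate explanation for the spread within genotypes is a piece of fat with lymphoid tissue in single samples. Over the 12 deviations from the group means, the adipocyte and B cell lists went together with a Pearson r of 0.816 (permutation p = 0.0045, also 0.0045 after adjustment over the 2 relations tested) and a Spearman rho of 0.685 (permutation p = 0.032). Without HuR replicate 2 and control replicate 2, r was 0.497, so the relation rests on those samples. It speaks to single samples and leaves open, as untested, whether the genotype itself changed the fat content of the pancreas.

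Other splits of the 12 arrays into groups of 6 were counted, 100 with the real one included. The real counts of called genes, overall and at 2-fold, were 0, which all 100 splits reach by construction (highest other 2 and 1), so these 2 counts say nothing about chance. At an unadjusted p under 0.05, 24 splits gave at least the real 1657 genes, the highest other giving 4749. Why this count varied so widely between splits was not tested. For gene lists called by camera with a preset correlation, 11 splits reached the real 16, the highest other giving 20 and the median of the others 9. Chance is therefore not excluded for the genes at an unadjusted p or for the called lists. For the size of the interferon list difference 3 splits, fewer than 5 in 100, reached the real 0.751, the highest other giving 0.845. The list was picked from 32, and after adjustment over them its exact permutation p was 0.139 and its camera p with an estimated correlation 0.193, so chance is not excluded for it either.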

How the results depend on the processing

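The adipocyte covariate, the omission of control replicate 2 and HuR replicate 2 together, the omission of plateau genes the exact permutation of list means, the omission of each list's member with the largest difference and the threshold of 0.1 with arrays left out or covariates were chosen after seeing the data. Under every alternative run, limma called 0 genes at an adjusted p under 0.05. At 0.1 it called 0 over all 12 arrays, but Gm7003 passed without HuR replicate 2 and Lgals9 without HuR replicate 4. The smallest adjusted p ran from 0.0577 without HuR replicate 2 to 0.987 without HuR replicate 6. Over the alternatives Elavl1 stayed higher in HuR samples, by 0.155 to 0.275. With single arrays left out it differed by 0.193 to 0.275, the genes at an unadjusted p under 0.05 numbered 1326 to 2206, and camera called 14 to 19 lists. The islet covariate gave 2893 genes at an unadjusted p under 0.05 against 1657, and the cause was not tested.

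Called lists fell from 16 to 10 with the adipocyte covariate, and to 0 with an estimated correlation and 0 by exact permutation of list means, both of which count the correlation between genes of a list. Of the 16 calls, the adipocyte covariate kept 6, lost 8 and reversed complement, and the adipocyte list has no value there, while matrix, stellate cells (-0.471) and B cells were newly called, all lower. Under the adipocyte covariate 4 lists reversed, to 0.0243 for acinar transcription factors, -0.295 for matrix, -0.123 for B and plasma cells and -0.189 for complement. The chemokine list mean also turned, to -0.0779, with its call lost while camera's direction stayed higher. The cause was not tested. The matrix list also reversed without HuR replicate 2, at -0.129, within a range of -0.129 to 0.133 over single arrays left out. A list used as a covariate has no value under its own setting. Of the other list values 748 kept their side of the threshold, 45 lost a call and 29 gained 1, where a change of sign between values that were both not called counts as kept. All 1881 values of named genes stayed on their side of the threshold, since none was called.

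Whether the replicate numbers mark pairs is not settled. Of 6 same-numbered pairs, 3 deviated together with a correlation over 0.1, the highest 0.636 for replicate 2, against a mean of -0.022 for other pairs. Of 12 arrays, 4 correlated best with their own number. A replicate block gave 0 called genes with a smallest limma adjusted p of 0.133. It gave 2270 genes at an unadjusted p under 0.05, 17 called lists and an Elavl1 difference of 0.239. Signal over background limits the T and NK cell, neutrophil, mast cell and liver lists, most of whose members lie below the median row, and saturation limits the digestive enzymes.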

Other observations

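All tests of the trypsin-family genes were chosen after the result was seen, and so was the omission of both far arrays, and the genes and segments in this part were chosen after their values were seen. Immunoglobulin variable segments were higher in HuR samples in 183 of 199 measured rows, 59 of them at an unadjusted p under 0.05, with 1 lower at that level. Their mean was 6.90 ± 1.20 (SD, n = 6) against 5.70 ± 0.85 (SD, n = 6), a difference of 1.19 (SE 0.60) with an exact permutation p of 0.0628. Without control replicate 2 and HuR replicate 2 the difference was 1.09, with an exact permutation p of 0.00794. This is the smallest p the remaining arrays can give, as the genotypes no longer overlapped. Control replicate 2, at 7.339, lay above most HuR arrays, and HuR replicate 2, at 9.05, was the highest array. Among the remaining arrays the lowest HuR array stood at 5.649 and the highest control at 5.63, so the separation was narrow. The omission of either array alone was not tested for the segments. The segments are close relatives. The heavy chain gene Ighm differed by 1.94 (SE 1.32), or -0.196 to 2.87 over the alternatives. Jchain, also in the B and plasma cell list, differed by 1.72 (SE 0.569), with a limma adjusted p over all genes of 0.878. The B cell receptor gene Cd79a was at 5.22 in both genotypes, a difference of -0.001 (SE 0.207).

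Further single genes had large differences, and none passed the threshold. The zinc transporter gene Slc39a5 differed by -0.75 (SE 0.197, exact permutation p 0.00649), Wars, the tryptophanyl-tRNA synthetase gene, by -0.84 (SE 0.239, exact permutation p 0.00649), the amino acid transporter gene Slc38a5 by -0.84 (SE 0.306, exact permutation p 0.0303) and the hepcidin genes Hamp and Hamp2 by -0.95 (SE 0.364) and -1.05 (SE 0.424). Without both far arrays Hamp and Hamp2 differed by -0.737 and -0.756. Obp2b, an odorant-binding protein gene, was 3.59-fold higher, at 1.845 (SE 0.558), and separated the genotypes in 6 of 6 HuR arrays. It stood at 10.123 in HuR replicate 2 against at most 7.805 in the other HuR arrays. Without both far arrays Obp2b differed by 1.3 (SE 0.301). The proliferation marker Mki67 differed by 1.13 (SE 0.553, exact permutation p 0.0541), and by 0.731 without both far arrays. With limma the adjusted p of these genes ran from 0.878 to 0.905.

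The interferon list difference of 0.751 (SE 0.247) was weighed against technical explanations. Without the 2 arrays far from the rest it was 0.69 (SE 0.222). Each is the highest of its group in this list, so leaving out both cannot show what either carries. With single arrays left out it ran from 0.605 without HuR replicate 2 to 0.873 without HuR replicate 4, so no single array removes it. A shift of all values between arrays (0.764, SE 0.263, after centring) does not account for it, nor does the mixture of sexes (0.772, SE 0.263, with Xist as a covariate). Adipose and lymphoid tissue taken along stays open, since with both list means as covariates the difference was 0.53 (SE 0.236), or 70.6%, and more macrophages stay open too, since with their list mean it was 0.388 (SE 0.165), or 51.7%. In each of these the SE spans the bound set before the test, so interferon response and cell content cannot be told apart with 12 arrays. An effect of elevated HuR, which the design names, may contribute to either and was not tested separately.

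Of 11 trypsin-family rows, 9 stood at the upper end of the scale on all 12 arrays, which hides their differences. The other 2 were 1810009J06Rik, 21.6-fold higher at 4.43 (SE 1.37), and Gm2663, 20.1-fold higher at 4.33 (SE 1.35), with exact permutation p of 0.0152 and 0.013 and limma adjusted p of 0.878. Without control replicate 2 and HuR replicate 2 they differed by 3.35 (SE 1.19) and 3.24 (SE 1.15). They are neighbours on chromosome 6 beside the trypsinogen genes, and 1810009J06Rik ran from 6.63 in control replicate 6 to 17.63 in HuR replicate 2. Probes shared between the 2 genes are a candidate explanation for their agreement, as they went together within genotypes with a Pearson r of 0.9979 (permutation p = 2e-05, adjusted 4e-05) and a Spearman rho of 0.965 (permutation p = 0.00011), and r was 0.996 without HuR replicates 2 and 6, though joint regulation of neighbours would give the same. The range of the pair was 11 on the log2 scale, which argues against a constant spill-over from the abundant trypsinogens. Spill-over that varies as widely cannot be told apart, because the trypsinogens stood at the upper end of the scale on all 12 arrays and hide any variation. An effect of the genotype on this pair was not tested separately.

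Xist was above 14 in control replicates 4 and 5 and in HuR replicates 1, 2 and 4. The Y-linked gene Uty was at 7.42 or more in control replicates 1, 2 and 3 and HuR replicates 3, 5 and 6, and at 5.14 or less elsewhere. Control replicate 6 had low values of both, with Xist at 5.53, Uty at 4.69, Kdm5d at 4.91 and Eif2s3y at 4.95.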
